A study of Homo sapiens with 12 samples.

How the data were processed

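RNA from 12 libraries of SW480 cells was enriched with oligo(dT) beads and made into libraries with a NEBNext Ultra II RNA kit, per the labels' protocols. The submitters' processing notes name fastp, STAR, DESeq2 and the hg38 genome, with no versions, and the counting program, its strand setting and the annotation are not given in the sources used here. The deposited tables give whole-number read counts per gene and library, per the file headers, which sum to between about 32617000 and 39019000 per library. The knockout table lists 29667 genes and the inhibitor one lists 30478, with 26814 in both. Each listed gene has at least 2 reads over its 6 libraries. The span and the summed exon length of all 33331 listed genes equal those of GENCODE release 29, which was used for coordinates, transcript length and overlaps. The authors' deposited tables also hold a log2 fold change and a p-value with an adjusted p-value for each gene, which served only to set their calls beside those made here. Normalized and FPKM columns, 24 in all, were not used.

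Columns were matched to groups by name. One inhibitor column carries no replicate number, so it was used as a replicate of its group with no number. Each of the 4 groups has 3 libraries.

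The counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM scaling, filterByExpr with default settings, Benjamini-Hochberg adjustment, threshold 0.05). The knockout comparison was coded EGFP minus ALDH1B1 and the inhibitor comparison inhibitor minus DMSO. Each was fitted on its own 6 libraries with no covariate. The difference between them was tested as an interaction on all 12 libraries. Standard errors of genes were computed from the F statistic, and those of list medians by resampling the members of the list. CPM used TMM-scaled library sizes.

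Before the data were examined, 42 gene lists were fixed, covering metabolism, growth, stress, signalling, differentiation, immunity and markers of other cell types. They were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, for lists with at least 5 tested members, and again with an estimated correlation. The genes named were also fixed by rule at that time: ALDH1B1, the 6 largest rises and 6 largest falls past 0.05 with a mean of at least 5 CPM and groups that do not overlap, and the 3 largest changes past 0.05 at that level in each of the 8 lists with the smallest camera p. To these were added the 4 genes per direction with the largest smaller change among those called in both comparisons, the 4 opposite calls with the smallest p for the difference, and called members of the aldehyde dehydrogenase family. Genes named outside the rule are marked as chosen after their values were seen. One gene that the rule selected is not reported here.

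Overlap of calls was set against the product of the 2 list sizes over the genes tested in both, with a two-sided Fisher exact test. Exons shared with any other annotated gene were taken as a percentage of the principal transcript, on either strand. The percentage counts all overlapping genes together, and a gene named beside it is the one with the longest single overlap.

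Alternatives were relative log expression size factors, no filter on low counts, DESeq2 1.42.0, a replicate block, 1 fit over all 12 libraries, each library left out in turn, an estimated correlation and fry for lists, and a minimum mean of 5 CPM for the correlation. One more was added after the data were seen, an offset that removes from each library a smooth trend over transcript length and GC content, fitted with mgcv 1.9.3 on genes outside the growth and respiration lists. A comparison of the clone carrying ALDH1B1 with the parental line in DMSO, normalised jointly, a list of aryl hydrocarbon receptor targets and the aldehyde dehydrogenase list without ALDH1B1 were also added after the data were seen.

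The tests were run on simulated counts with 100 genes changed 1.5-fold and 100 changed 2-fold before use. At 1.5-fold and 2-fold, 97% and 100% of changed genes were recovered for the knockout comparison (17162 genes) and 95% and 100% for the inhibitor comparison (17536 genes). For the difference, 83% and 97% were recovered (18796 genes). False calls were 21 of 218, 16 of 211 and 12 of 192, above the nominal rate. A simulated length trend alone, over 17505 genes of the inhibitor comparison, gave an unchanged respiratory chain list a median of -0.12 without the offset and passed it. With the offset that list did not pass (camera, Benjamini-Hochberg adjusted p = 0.91), while a list truly lowered by -0.25 kept a median of -0.24. The simulated trend was steeper than the real one of the inhibitor comparison, with medians of -0.14 under 800 nt and -0.012 between 800 and 1500 nt. The simulated -0.12 therefore does not show how far the real trend could lower the list.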

Results

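Polyadenylated RNA was sequenced from SW480 cells, a human colorectal adenocarcinoma line, in 4 groups of 3 libraries. ALDH1B1 encodes a mitochondrial aldehyde dehydrogenase, an enzyme class that oxidises aldehydes to carboxylic acids. An ALDH1B1 knockout clone carried either an EGFP construct, a fluorescent protein used as the control, or an ALDH1B1 construct. The parental line was kept for 24 h with DMSO, the solvent control, or with 2 µM of an inhibitor described as selective for ALDH1B1. Each library held between about 32617000 and 39019000 counted reads. The series description gives 3 biological replicates per condition, so the p-values measure the spread between these cultures of 1 clone and 1 parental line. No pair of replicates agreed within sampling noise, since chi-square per degree of freedom over genes ran from 3.14 to 15.9. In the knockout clone EGFP replicate 3 stood apart, at 10.7 and 15.9 from the other EGFP libraries, which were at 3.98 from each other. In the parental line DMSO replicate 2 stood apart, at 10.3 and 6.93 from the other DMSO libraries, which were at 3.68 from each other.

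ALDH1B1 itself (ENSG00000137124, hg38 chromosome 9, 38392664 to 38398661, plus strand) was measured first. In the knockout clone its level was 18.4 ± 0.46 CPM (counts scaled to library size; SD, n = 3) with EGFP and 99.8 ± 3.0 CPM (SD, n = 3) with ALDH1B1. The log2 fold change was -2.44 (SE 0.05), with an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 5.9e-13, and the groups did not overlap. The EGFP libraries held 683, 636 and 635 ALDH1B1 reads, so the transcript was still present in the knockout clone. In the parental line the level was 50.045 ± 3.4 CPM (SD, n = 3) with DMSO and 50.5 ± 0.11 CPM (SD, n = 3) with the inhibitor. That difference of 0.01 (SE 0.06) on the log2 scale lay within the replicate spread (edgeR, Benjamini-Hochberg adjusted p = 0.94).

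**Figure D1:**
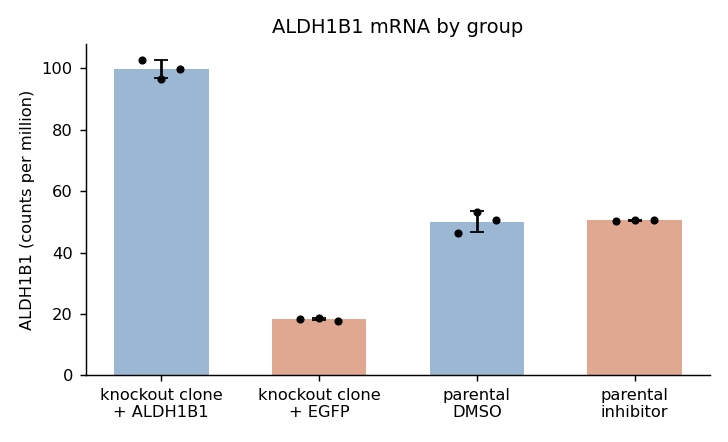
ALDH1B1 level in CPM (vertical axis) in the 4 groups, with bars for the mean, error bars for 1 SD and points for the 3 libraries of each group. The mean is 18.4 in the knockout clone with EGFP and 99.8 with ALDH1B1, and 50.045 and 50.5 in the parental line with DMSO and with the inhibitor.

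The first comparison asked which transcripts differ in the knockout clone between EGFP and ALDH1B1, and positive values mean higher without ALDH1B1 (EGFP minus ALDH1B1). With the construct ALDH1B1 mRNA was at 96.7 to 102.8 CPM, above the 46.3 to 53.1 CPM of the parental line with DMSO. Effects of its loss and of its excess therefore cannot be told apart here. Without ALDH1B1, lists of genes for the respiratory chain, both kinds of ribosome, ribosome assembly and DNA replication were lower by small amounts, although the 2 ribosomal lists did not pass with an estimated correlation between genes. Wnt target genes were higher, led by a secreted Wnt antagonist, NOTUM, at 0.99 (SE 0.07, n = 3 per group). Single genes named here as the largest changes of a comparison had a mean of at least 5 CPM and groups that did not overlap. Among the 6 largest rises were the pregnancy-specific glycoprotein genes PSG9, at 1.44 (SE 0.11), PSG5, at 1.39 (SE 0.07), and PSG1, at 1.22 (SE 0.09), all on chromosome 19. These paralogs are near-identical, so the split of reads among them is uncertain.

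The brain-type aldolase gene ALDOC rose by 1.26 (SE 0.12), from 3.52 ± 0.16 to 8.47 ± 1.0 CPM (SD, n = 3). QPRT, which encodes an enzyme of NAD synthesis from quinolinate and shares 24.4% of its transcript, rose by 1.17 (SE 0.08), and TREM2, a receptor gene best known from myeloid cells, by 1.17 (SE 0.13). After ALDH1B1 the largest falls were in ATP5ME, an ATP synthase subunit gene, at -1.39 (SE 0.15), TAX1BP3, at -1.16 (SE 0.15), RPL26, at -1.13 (SE 0.12), the pseudogene RPL21P28, at -1.10 (SE 0.23), and the lactate dehydrogenase gene LDHB, at -0.95 (SE 0.06). Several of these overlap other annotated genes. Of the principal transcript of ATP5ME (chromosome 4, 672436 to 674338) 49.9% is shared with other genes, MYL5 among them. The share is 74.1% in TAX1BP3, with a readthrough gene among the others, 38.7% in RPL26 and 64.6% in LDHB. How the authors' counting treated shared exons is not given in the sources used here, so these values are uncertain, as is that of RPL21P28, which resembles its parent gene. In each of these 11 genes the edgeR quasi-likelihood Benjamini-Hochberg adjusted p was 0.0043 or below and the groups did not overlap, which chance gives 10% of genes.

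Across 17404 genes tested, 3059 passed an adjusted p of 0.05 with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 1455 higher and 1604 lower without ALDH1B1. The median absolute log2 fold change of these genes was 0.28, and 166 changed at least 2-fold, 145 up and 21 down. The count fell to 1371, 1670 and 1907 on leaving out ALDH1B1 replicate 2, ALDH1B1 replicate 1 and EGFP replicate 1. DESeq2 gave 85 genes changed at least 2-fold, against 166.

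Nuclear-encoded respiratory chain and ATP synthase genes fell as a group. Of 77 tested, 47 fell and none rose (58 fell adjusted over the list alone). The median was -0.20 (camera, Benjamini-Hochberg adjusted p = 8.6e-25, and adjusted p = 0.035 with an estimated correlation). Besides ATP5ME, the complex I genes NDUFA11 and NDUFA1 fell by 0.76 (SE 0.08) and 0.68 (SE 0.12), with 67.0% and 44.5% of their transcripts shared with another gene. Cytosolic ribosomal protein genes fell in 45 of 79 cases (53 adjusted over the list alone). The median was -0.17 (camera, Benjamini-Hochberg adjusted p = 1.4e-22, but adjusted p = 0.13 with an estimated correlation). RPS29 fell by 0.94 (SE 0.14) and RPL38 by 0.60 (SE 0.08), both from families with many processed pseudogenes, and RPL38 shares 57.8% of its transcript. Mitochondrial ribosomal protein genes fell in 39 of 77 cases (49 adjusted over the list alone). The median was -0.18 (camera, Benjamini-Hochberg adjusted p = 1.9e-15, adjusted p = 0.071 with an estimated correlation). In that list MRPL52 fell by 0.54 (SE 0.11), MRPS21 by 0.43 (SE 0.09) and MRPL12 by 0.76 (SE 0.17), the last losing its call with DESeq2 and sharing 68.2% of its transcript with another gene.

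Short transcripts in general were lower without ALDH1B1. Among 118 genes outside the growth and respiration lists with a principal transcript under 800 nt, the median log2 fold change was -0.17. Relative to the mean of the 6 libraries, these genes stood at 0.13, 0.09 and 0.04 in the libraries with ALDH1B1 and at -0.06, -0.04 and -0.16 in those with EGFP. This shift moves with the same groups as the respiratory chain and ribosomal lists. EGFP replicate 3, the lowest, also had the highest share of mitochondrially encoded reads of these 6 libraries, 5.02%, but the respiratory chain and cytosolic ribosomal lists still passed as lower without it.

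**Figure D2:**
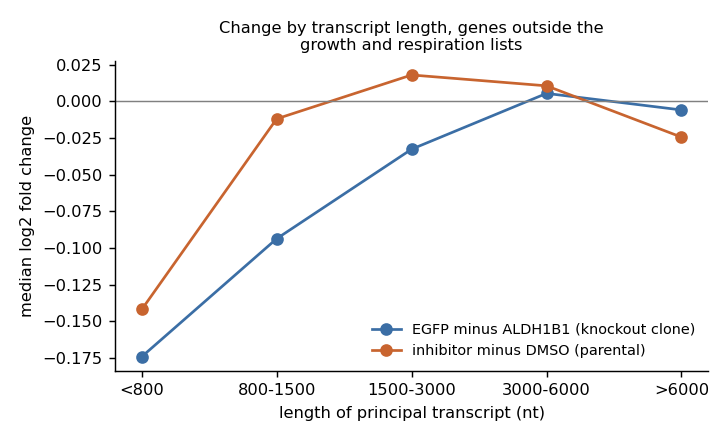
Median log2 fold change (vertical axis) of genes outside the growth and respiration lists, by length of the principal transcript in nt (horizontal axis), in blue for EGFP minus ALDH1B1 and in orange for inhibitor minus DMSO. Points are medians with no error bars, at -0.17 and -0.14 under 800 nt and at -0.094 and -0.012 between 800 and 1500 nt.

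Genes of ribosome assembly fell in 35 of 62 cases and rose in none (43 fell adjusted over the list alone). The median was -0.20 (camera, Benjamini-Hochberg adjusted p = 5.6e-18, adjusted p = 0.035 with an estimated correlation). EBNA1BP2 fell by 0.45 (SE 0.05), the U3 particle gene RRP9 by 0.42 (SE 0.06) and RRP1 by 0.37 (SE 0.06). Genes of the G1/S transition and DNA replication fell in 29 of 44 cases and rose in none (34 fell adjusted over the list alone). The median was -0.19 (camera, Benjamini-Hochberg adjusted p = 7.3e-16, adjusted p = 0.035 with an estimated correlation, but adjusted p = 0.063 with the length and GC trend removed as well). Among them POLA2, a DNA polymerase alpha subunit gene that shares 53.7% of its transcript with another gene, fell by 0.49 (SE 0.08), the replication initiation gene MCM10 by 0.39 (SE 0.07) and UHRF1, which is needed to maintain DNA methylation, by 0.39 (SE 0.05). MYC targets fell in 17 of 30 cases and rose in 2 (19 and 2 adjusted over the list alone). This list shares 6 members with the ribosome assembly list, NOP56 among them, so the falls of these lists are not independent. The median was -0.19 (camera, Benjamini-Hochberg adjusted p = 3.4e-10, adjusted p = 0.035 with an estimated correlation), including NME1 at -0.56 (SE 0.07) and NOP56 at -0.34 (SE 0.04). NME1 shares 44.5% of its transcript with other genes, a readthrough gene among them. MYC itself, named after its value was seen, was 1 of the 2 members that rose, at 0.17 (SE 0.04).

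Heat shock genes fell in 10 of 19 cases and rose in none (11 fell adjusted over the list alone). The median was -0.15 (camera, Benjamini-Hochberg adjusted p = 2.1e-09, adjusted p = 0.035 with an estimated correlation). The chaperone genes CHORDC1 and HSPH1 fell by 0.38 (SE 0.05) and 0.32 (SE 0.04), and HSPA1A, which has the near-identical copy HSPA1B, by 0.35 (SE 0.07). Mitochondrial chaperone and import genes fell in 17 of 29 cases (20 adjusted over the list alone). The median was -0.18 (camera, Benjamini-Hochberg adjusted p = 5.9e-11, adjusted p = 0.071 with an estimated correlation), among them HSPE1 at -0.71 (SE 0.07), TIMM10 at -0.45 (SE 0.07) and TIMM13 at -0.44 (SE 0.09). HSPE1 shares 49.8% of its transcript with other genes, HSPD1 among them, and TIMM13 shares 28.9%, so both values are uncertain through overlap. Genes of the G2/M phase and mitosis fell in 16 of 48 cases (19 adjusted over the list alone). The median was -0.12 (camera, Benjamini-Hochberg adjusted p = 2.7e-08, but adjusted p = 0.25 with an estimated correlation).

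Wnt targets rose in 11 of 26 cases and fell in 1 (13 and 3 adjusted over the list alone). The median was 0.14 (camera, Benjamini-Hochberg adjusted p = 1.9e-06, adjusted p = 0.035 with an estimated correlation). NOTUM went from 64.8 ± 4.1 to 128 ± 13.4 CPM (SD, n = 3), and another secreted Wnt antagonist gene, DKK4, rose by 0.91 (SE 0.10). Interferon-induced genes rose in 12 of 37 cases and fell in 1 (17 and 1 adjusted over the list alone). The median was 0.26 (camera, Benjamini-Hochberg adjusted p = 1.8e-05, but adjusted p = 0.13 with an estimated correlation), including OAS1 at 0.66 (SE 0.15) and IFITM1 at 0.40 (SE 0.06). IFITM1 shares 41.1% of its transcript with other genes, IFITM2 among them. Cholesterol synthesis genes rose in 8 of 25 cases and fell in 1 (8 and 2 adjusted over the list alone). The median was 0.09 (camera, Benjamini-Hochberg adjusted p = 5.5e-04, but adjusted p = 0.19 with an estimated correlation), led by STARD4 at 0.60 (SE 0.05) and INSIG1 at 0.48 (SE 0.05). Fibroblast markers, included as a check for another cell type, rose in 5 of 8 cases (5 adjusted over the list alone). The median was 0.59 (camera, Benjamini-Hochberg adjusted p = 3.1e-04, adjusted p = 0.071 with an estimated correlation). Of these PDGFRB went from 6.06 ± 0.81 to 11.5 ± 1.1 CPM (SD, n = 3) and FBLN1 from 18.0 ± 0.30 to 26.2 ± 0.86 CPM (SD, n = 3). The genes named in these 4 lists were chosen after their values were seen.

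Of the aldehyde dehydrogenase family, 6 of 15 tested genes rose besides the fall of ALDH1B1 (6 and 1 adjusted over the list alone): ALDH3B1 by 0.47 (SE 0.07), ALDH6A1 by 0.31 (SE 0.05), ALDH5A1 by 0.27 (SE 0.07), ALDH2 by 0.25 (SE 0.07), ALDH7A1 by 0.23 (SE 0.05) and ALDH3A2 by 0.16 (SE 0.05). As a group the family did not pass (camera, Benjamini-Hochberg adjusted p = 0.57), and its median of 0.16 and mean of 0.00 were not negative while the test pointed down, since the list holds ALDH1B1 itself. Without ALDH1B1 in the list, a test chosen after the values were seen, the other 14 tested members had a median of 0.19 (camera, Benjamini-Hochberg adjusted p = 0.0018, but adjusted p = 0.17 with an estimated correlation). The calls of ALDH2, ALDH3A2 and ALDH5A1 ended on leaving out ALDH1B1 replicate 1, where ALDH5A1 was at 0.21 (edgeR, Benjamini-Hochberg adjusted p = 0.088). Those of ALDH2 and ALDH3A2 also ended without ALDH1B1 replicate 2 (edgeR, Benjamini-Hochberg adjusted p = 0.11 and 0.14) or EGFP replicate 1, those of ALDH5A1 and ALDH3A2 without ALDH1B1 replicate 3, and that of ALDH3A2 without EGFP replicate 2 or with no filter on low counts.

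In all, 19 of 41 lists passed camera, 11 lower and 8 higher, and 6 passed with an estimated correlation. Among the latter, the ribosome assembly and MYC target lists share members. With the length and GC trend also removed 4 of these 6 passed, while the G1/S list did not, at a median of -0.20 in place of -0.19, nor did the heat shock list, at -0.15 both before and after (camera with an estimated correlation, Benjamini-Hochberg adjusted p = 0.063 and 0.069). With the preset correlation both passed after removal (camera, Benjamini-Hochberg adjusted p = 3.7e-18 and 2.7e-10). The remaining lists past 0.05 with the preset correlation were absorptive enterocyte markers (3 of 7 rose, 5 adjusted over the list alone), mitochondrially encoded genes (3 of 13 rose and 1 fell, 7 and 1 adjusted over the list alone), mesenchymal genes (8 of 27 rose and 4 fell, 9 and 4 adjusted over the list alone) and lysosomal genes (8 of 31 rose, 9 and 2 lower adjusted over the list alone), all higher. Citric acid cycle genes (6 of 23 fell, 6 adjusted over the list alone) and epithelial junction genes (6 of 26 fell and 1 rose, 7 and 2 adjusted over the list alone) were lower. In the order given these had camera Benjamini-Hochberg adjusted p of 0.010, 0.036, 0.036, 0.043, 0.016 and 0.020, and adjusted p = 0.28, 0.65, 0.18, 0.18, 0.22 and 0.14 with an estimated correlation. The mesenchymal list lost its call without ALDH1B1 replicates 1 or 3 or EGFP replicate 2, the lysosomal list without ALDH1B1 replicates 1, 2 or 3 or EGFP replicate 1, and the mitochondrially encoded list without ALDH1B1 replicates 2 or 3 or EGFP replicate 3, with camera Benjamini-Hochberg adjusted p up to 0.13, 0.080 and 0.40. The lysosomal list also lost it with relative log expression size factors (camera, Benjamini-Hochberg adjusted p = 0.054). Other divisions of the same 6 libraries gave up to 18 lists with the preset correlation but at most 0 genes, and genes of a list are not independent replicates. Those divisions mix the groups, which puts real changes into the replicate spread, so their low gene count is largely built in.

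**Figure D3:**
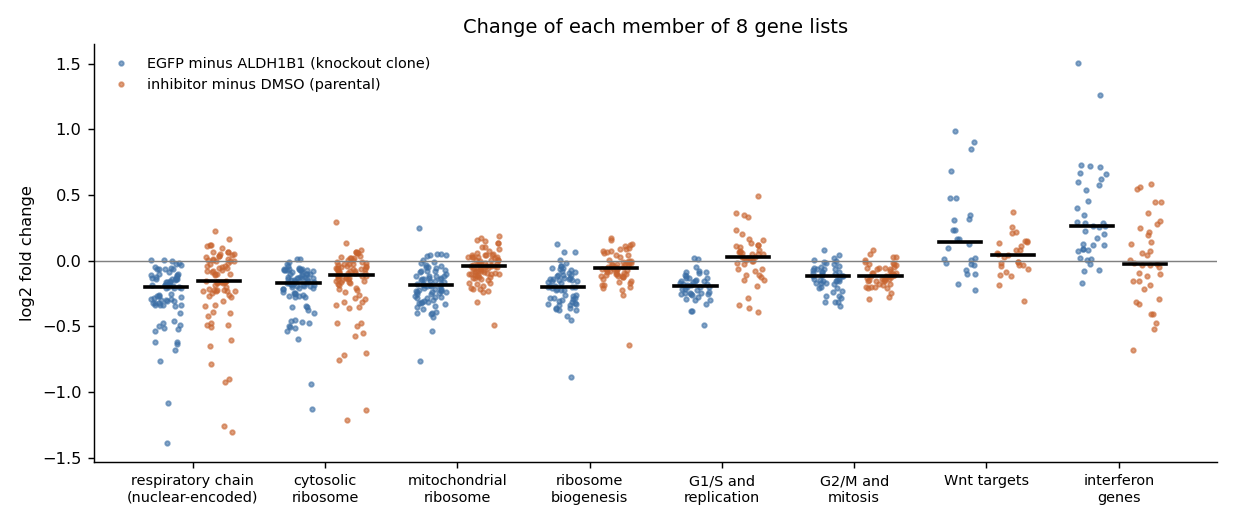
Log2 fold change (vertical axis) of each tested member of 8 gene lists, with points for genes, black lines for medians, blue for EGFP minus ALDH1B1 in the knockout clone and orange for inhibitor minus DMSO in the parental line. Medians of the respiratory chain list are -0.20 and -0.15, and those of the G1/S and replication list are -0.19 and 0.03.

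The second comparison asked what 24 h of ALDH1B1 inhibition changes in the parental line, and positive values mean higher with the inhibitor (inhibitor minus DMSO). CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610), a cytochrome P450 gene and the classic target of the aryl hydrocarbon receptor, had the largest rise within the limits given above, from 7.51 ± 1.8 to 20.9 ± 2.4 CPM (SD, n = 3), or 1.47 (SE 0.14) on the log2 scale. The transcription factor gene KLF15 rose by 0.70 (SE 0.11), the tight junction gene TJP3 by 0.61 (SE 0.12), CDK18 by 0.59 (SE 0.10), the interferon-induced gene IFI6 by 0.58 (SE 0.13) and the keratin gene KRT6A, which has close paralogs, by 0.58 (SE 0.13). DCLK1, a marker of tuft cells, fell by 1.03 (SE 0.14), from 17.6 ± 4.0 to 8.62 ± 1.2 CPM (SD, n = 3).

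Within the same limits of level and overlap the largest falls were in ATP5ME, at -1.31 (SE 0.13), NDUFB8, at -1.26 (SE 0.14), RPS29, at -1.21 (SE 0.14), LDHB, at -1.19 (SE 0.07), BLOC1S1, at -1.15 (SE 0.11), and RPL26, at -1.14 (SE 0.06). Of their principal transcripts 49.9%, 71.7%, 0%, 64.6%, 64.1% and 38.7% are shared with another annotated gene, so apart from RPS29, which has pseudogene copies, these are uncertain through overlap. All 13 genes named here had an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.021 or below and groups that did not overlap, which chance gives 10% of genes. Without DMSO replicate 3 the calls of TJP3, IFI6 and KRT6A ended, at 0.60, 0.48 and 0.54 (edgeR, Benjamini-Hochberg adjusted p = 0.070, 0.12 and 0.11), and those of IFI6 and KRT6A also ended without inhibitor replicate 3 or the inhibitor library with no number. KRT6A also lost its call in a fit over all 12 libraries, as did MKI67 and MT-CO2 of the lists described next.

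Of 17848 genes tested, 712 passed an adjusted p of 0.05 with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 338 higher and 374 lower with the inhibitor. Their median absolute log2 fold change was 0.32, and 29 changed at least 2-fold, 3 up and 26 down. Leaving out DMSO replicate 3, inhibitor replicate 3 or the unnumbered inhibitor library left 171, 178 and 447 genes, and no filter on low counts gave 1402. One fit over all 12 libraries turned the balance to 590 higher and 431 lower, and without DMSO replicate 2 it was 175 higher and 303 lower.

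Cytosolic ribosomal protein genes fell in 19 of 79 cases and rose in none (38 fell and 2 rose adjusted over the list alone). The median was -0.11 (camera, Benjamini-Hochberg adjusted p = 7.1e-19, but adjusted p = 0.44 with an estimated correlation). Besides RPS29 and RPL26, RPS27 fell by 0.76 (SE 0.09). Nuclear-encoded respiratory chain genes fell in 26 of 77 cases and rose in none (38 and 3 adjusted over the list alone). The median was -0.15 (camera, Benjamini-Hochberg adjusted p = 3.2e-18, but adjusted p = 0.44 with an estimated correlation), NDUFB1 by 0.93 (SE 0.12). Among the 49 members with under 10% of their transcript shared, and with the length and GC trend removed, the median was 0.01 and the list did not pass (limma's camera, Benjamini-Hochberg adjusted p = 0.086 over 14 such tests). Short transcripts in general were lower here too: 116 genes under 800 nt outside these lists had a median of -0.14, with the libraries at 0.06, 0.06 and 0.11 with DMSO and at -0.08, -0.13 and -0.02 with the inhibitor.

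Mitochondrially encoded genes fell in 3 of 13 cases (6 adjusted over the list alone). The median was -0.17 (camera, Benjamini-Hochberg adjusted p = 2.8e-07, but adjusted p = 0.44 with an estimated correlation and, in another fit, adjusted p = 0.15 with the length and GC trend removed). MT-ND3 fell by 0.91 (SE 0.09), from 915 ± 28.0 to 486 ± 91.2 CPM (SD, n = 3). MT-ND6 fell by 0.21 (SE 0.05) and MT-CO2 by 0.19 (SE 0.04), and both lost their calls when that trend was removed. Both calls also ended without DMSO replicate 1, DMSO replicate 3 or inhibitor replicate 3, with edgeR Benjamini-Hochberg adjusted p up to 0.15. Genes of G2/M and mitosis fell in 5 of 48 cases (14 adjusted over the list alone), with a median of -0.11 and 43 of 48 below 0 (camera, Benjamini-Hochberg adjusted p = 6.5e-08, but adjusted p = 0.44 with an estimated correlation). The 3 called members with the largest falls were UBE2C, at -0.29 (SE 0.05), MKI67, at -0.27 (SE 0.07), and CKS2, at -0.25 (SE 0.06), and each lost its call on leaving out DMSO replicate 3. Both MKI67 and CKS2 also lost it without DMSO replicate 2, inhibitor replicate 1 or inhibitor replicate 3 (edgeR, Benjamini-Hochberg adjusted p = 0.13 and 0.19 without the last), MKI67 without the unnumbered inhibitor library, and CKS2 stood at -0.016 with the length and GC trend removed. The list itself stayed lower then, at a median of -0.089 (camera, Benjamini-Hochberg adjusted p = 3.7e-07, but adjusted p = 0.45 with an estimated correlation).

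Cholesterol synthesis genes rose in 3 of 25 cases (4 adjusted over the list alone). The median was 0.07 (camera, Benjamini-Hochberg adjusted p = 0.011, but adjusted p = 0.49 with an estimated correlation). The members that rose included FDFT1, by 0.23 (SE 0.06), and SREBF2, by 0.23 (SE 0.06), each losing its call without DMSO replicate 2, DMSO replicate 3 or inhibitor replicate 3, with edgeR Benjamini-Hochberg adjusted p up to 0.21. The call of FDFT1 also ended without the unnumbered inhibitor library, that of SREBF2 without inhibitor replicate 1, and that of the list without inhibitor replicate 3 (camera, Benjamini-Hochberg adjusted p = 0.096). The aldehyde dehydrogenase family had 16 of 17 members above 0 and a median of 0.09 (camera, Benjamini-Hochberg adjusted p = 0.011, but adjusted p = 0.44 with an estimated correlation), with ALDH1A3 up by 0.32 (SE 0.05) and ALDH6A1 by 0.31 (SE 0.07) as the 2 that passed on their own (2 adjusted over the list alone). ALDH1A3 shares 42.0% of its transcript with another gene, and ALDH6A1 lost its call without DMSO replicate 3 (edgeR, Benjamini-Hochberg adjusted p = 0.082), DMSO replicate 2 or the unnumbered inhibitor library. ATF4 targets rose in 4 of 41 cases (5 and 1 lower adjusted over the list alone). The median was 0.05 (camera, Benjamini-Hochberg adjusted p = 0.030, but adjusted p = 0.49 with an estimated correlation), including DDIT4, which shares 48.5% of its transcript, at 0.37 (SE 0.05). Without the unnumbered inhibitor library the aldehyde dehydrogenase and ATF4 lists lost their calls (camera, Benjamini-Hochberg adjusted p = 0.059 and 0.17), and the ATF4 list also did without DMSO replicate 2 or with the length and GC trend removed.

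Nuclear noncoding RNAs fell in 3 of 7 cases (3 adjusted over the list alone). The median was -0.28 (camera, Benjamini-Hochberg adjusted p = 0.0021, but adjusted p = 0.44 with an estimated correlation), among them MALAT1 at -0.47 (SE 0.11) and SNHG1 at -0.28 (SE 0.04). MALAT1 lost its call with DESeq2, with the length and GC trend removed and without DMSO replicate 3, inhibitor replicate 3 (edgeR, Benjamini-Hochberg adjusted p = 0.13) or the unnumbered inhibitor library. Secretory lineage markers fell in 2 of 13 cases, DCLK1 among them (3 adjusted over the list alone). The median was -0.21 (camera, Benjamini-Hochberg adjusted p = 0.0080, but adjusted p = 0.44 with an estimated correlation). YAP targets fell in 1 of 21 cases (2 adjusted over the list alone) and mesenchymal genes in 3 of 25, with 1 higher (7 and 1 adjusted over the list alone), with medians of -0.13 and -0.08 (camera, Benjamini-Hochberg adjusted p = 0.013 and 0.020, but adjusted p = 0.44 in both with an estimated correlation). AXL, in both lists, was at -0.46 (SE 0.11) and lost its call without inhibitor replicate 3 (edgeR, Benjamini-Hochberg adjusted p = 0.13), DMSO replicate 3 or DMSO replicate 2. The YAP list lost its call without DMSO replicate 2 and the mesenchymal list without the unnumbered inhibitor library (camera, Benjamini-Hochberg adjusted p = 0.067 and 0.064). AXL and DDIT4 were chosen after their values were seen. Together 11 of 42 lists passed camera and 0 did with an estimated correlation, while other divisions of the 6 libraries gave up to 10 lists and at most 1 gene. That low gene count is again largely built in, since those divisions mix the groups.

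The 2 comparisons share no library, and both are meant to set low against high ALDH1B1 activity, so their changes were set side by side. That activity was not measured here. ALDH1B1 mRNA was at 96.7 to 102.8 CPM in the clone with ALDH1B1, above the 46.3 to 53.1 CPM of the parental line with DMSO. Among 16093 genes tested in both, 169 were lower in both, where 35.7 would be shared by independent lists, and 73 were higher in both, against 27.6 (two-sided Fisher exact p = 4.6e-75 and 6.9e-15, with genes taken as independent, which they are not). Opposite calls were made for 34 genes, against 62.8 from independent lists, but for 64 against 51.3 with DESeq2 and 115 against 90.6 with no filter on low counts, so whether they are fewer than expected depended on the tool and the filter. They numbered 57 with the length and GC trend removed, against 86.9 from independent lists, and 20, 22, 5, 6 and 16, against 34.1, 27.7, 14.4, 15.3 and 39.0, without ALDH1B1 replicates 1 and 2, DMSO replicate 3, inhibitor replicate 3 and the unnumbered inhibitor library. Across genes the fold changes correlated weakly, with Pearson r of 0.17 (jackknife SD 0.079), Spearman rho of 0.19 and a covariance of 0.0124 (jackknife SD 0.00655), which is within 2 SD of 0. Among genes with a mean of at least 5 CPM r was 0.30, and it was 0.11 without EGFP replicate 2.

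Among genes with a mean of at least 5 CPM, those lower in both were led by ATP5ME, RPL26, LDHB and RPS29, whose falls are given above for each comparison. Those higher in both were led by IFI6, at 0.58 (SE 0.14) without ALDH1B1 and 0.58 (SE 0.13) with the inhibitor, SPATA7, at 0.48 (SE 0.11) and 0.49 (SE 0.12), QPRT, at 1.17 (SE 0.08) and 0.47 (SE 0.11), and the stress cytokine gene GDF15, at 0.54 (SE 0.08) and 0.41 (SE 0.08). With the inhibitor each of these 4 lost its call on leaving out inhibitor replicate 3, where GDF15 stood at 0.40 (edgeR, Benjamini-Hochberg adjusted p = 0.054), and IFI6, SPATA7 and QPRT also without DMSO replicate 3 (edgeR, Benjamini-Hochberg adjusted p = 0.12, 0.14 and 0.11) or the unnumbered inhibitor library, and SPATA7 and QPRT without DMSO replicate 1. The knockout call of SPATA7 ended without ALDH1B1 replicate 2 (edgeR, Benjamini-Hochberg adjusted p = 0.061). Leaving out DMSO replicate 3 or inhibitor replicate 3 left 79 same-direction genes in place of 242, 13 of them higher, and DMSO replicate 2 left 159, 34 of them higher. Those higher in both numbered 43, 112 and 36 without ALDH1B1 replicate 2, EGFP replicate 3 and the unnumbered inhibitor library.

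**Figure D4:**
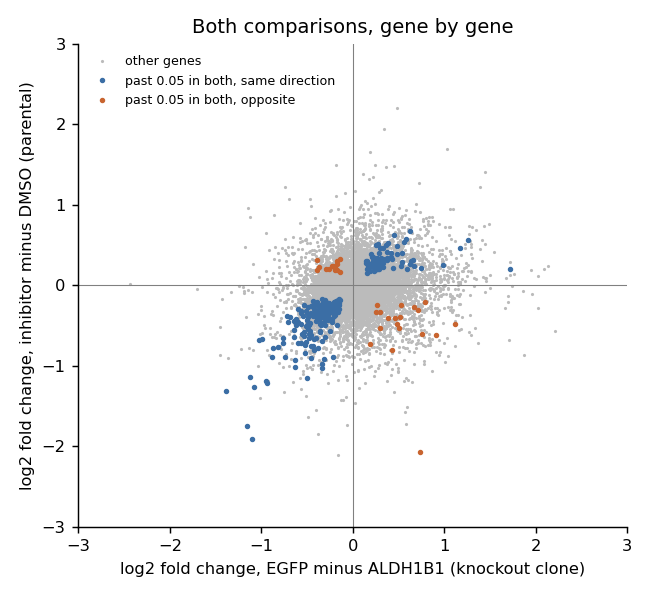
Log2 fold change of each of 16093 genes without ALDH1B1 in the knockout clone (horizontal axis) and with the inhibitor in the parental line (vertical axis), with 1 point per gene and 1 gene outside the axes. Blue points, 242 genes, passed 0.05 in both in the same direction and orange points, 34 genes, in opposite directions.

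The test of the difference between the comparisons over all 12 libraries passed 974 of 19075 genes (edgeR quasi-likelihood, Benjamini-Hochberg), 363 with a higher and 611 with a lower change without ALDH1B1 than with the inhibitor. Without DMSO replicate 2 that balance turned to 385 higher and 332 lower. The count was 392, 427, 526, 471, 601 and 594 on leaving out ALDH1B1 replicates 1 and 2, EGFP replicate 1, DMSO replicate 3, inhibitor replicate 3 and the unnumbered inhibitor library. The comparisons differ in cell background, clone against parental line, as well as in knockout against inhibitor. The design cannot separate these, so a difference cannot be assigned to either. Of genes called in opposite directions, the thioredoxin-binding protein gene TXNIP was at 0.51 (SE 0.05) without ALDH1B1 and -0.39 (SE 0.05) with the inhibitor, and the annexin gene ANXA1 at 0.49 (SE 0.06) and -0.48 (SE 0.06). The secreted factor genes MUCL1 and FGF19 were at 0.71 (SE 0.08) and -0.31 (SE 0.08), and at -0.39 (SE 0.04) and 0.19 (SE 0.05). These 4 genes were picked as the opposite calls with the smallest p in this same test, so that they pass it adds no support. Their edgeR Benjamini-Hochberg adjusted p for the difference was 2.9e-07 for TXNIP, 8.1e-06 for ANXA1, 5.0e-05 for MUCL1 and 1.6e-05 for FGF19. With the inhibitor the calls of MUCL1 and FGF19 ended without DMSO replicate 3, where their adjusted p from edgeR with Benjamini-Hochberg adjustment was 0.18 and 0.12, and also without DMSO replicate 2, inhibitor replicate 1 or inhibitor replicate 3. FGF19 lost its call without the unnumbered inhibitor library as well, and MUCL1 stood at -0.051 with the length and GC trend removed.

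The authors' deposited table for the knockout comparison held 2853 genes with an adjusted p under 0.05, 1114 higher and 1739 lower, of which 2640 were among the 3059 above. For the inhibitor the authors' deposited table held 939, 472 higher and 467 lower, of which 668 were among the 712.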

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

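The tests with the length and GC trend removed, the overlap among genes with little exon sharing, the repeats against protein-coding genes alone and the family list without ALDH1B1 were chosen only after the result was seen. In this section the SE of a list median comes from resampling members as if independent. It does not measure the spread between cultures.

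The change without ALDH1B1 differed from the change with the inhibitor, by the test of the difference itself over 12 libraries, for 26 named genes and 18 lists. The comparisons were made in different cell backgrounds, so the design cannot separate an effect of background from knockout against inhibition. Values are log2 change without ALDH1B1 minus log2 change with the inhibitor. ALDH1B1 stood at -2.48 (SE 0.09; edgeR, Benjamini-Hochberg adjusted p = 3.0e-15). The difference was positive for MUCL1 at 0.99, PSG1 at 0.99, ANXA1 at 0.94, TXNIP at 0.88, DKK4 at 0.77, NOTUM at 0.70, QPRT at 0.68, DCLK1 at 0.66, MALAT1 at 0.62, BLOC1S1 at 0.62, MT-ND3 at 0.57, STARD4 at 0.42 and MT-CO2 at 0.42. It was negative for HSPE1 at -0.36, HSPH1 at -0.38, RRP1 at -0.39, UHRF1 at -0.39, RRP9 at -0.40, MCM10 at -0.46, KLF15 at -0.59, EBNA1BP2 at -0.59, FGF19 at -0.61, MRPL12 at -0.76, CYP1A1 at -1.13 and KRT6A at -1.35. Of these, DCLK1, BLOC1S1, MT-ND3 and HSPE1 passed as lower in both comparisons, and NOTUM and QPRT as higher in both. The edgeR Benjamini-Hochberg adjusted p of these 25 genes was 0.043 or below. TXNIP, ANXA1, MUCL1 and FGF19 were themselves named for the smallest p in this test among opposite calls. Others were named as the largest changes of 1 comparison or of its lists. That choice by itself favours a difference from the other comparison, so their passing adds little support.

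Among lists the median difference was -0.25 for heat shock genes, -0.25 for G1/S and replication, -0.20 for mitochondrial chaperones and import, -0.19 for ribosome assembly, -0.18 for glycolysis and -0.16 each for mitochondrial ribosomal proteins, MYC targets and epithelial junctions. It was -0.13 for the citric acid cycle, -0.11 for the respiratory chain, -0.091 for immediate early genes, -0.069 for cytosolic ribosomal proteins and -0.00046 for the aldehyde dehydrogenase family, whose mean was -0.035. That call rests on ALDH1B1 itself, since the other 16 members had a mean of 0.12 and did not pass (camera, Benjamini-Hochberg adjusted p = 0.64). Higher medians were found for Wnt targets at 0.086, mesenchymal genes at 0.22, interferon-induced genes at 0.22, mitochondrially encoded genes at 0.36 and fibroblast markers at 0.70. The camera Benjamini-Hochberg adjusted p ran from 4.3e-16 to 0.046, and with an estimated correlation 1 of the 18 lists, heat shock, passed (adjusted p = 0.022 with an estimated correlation). The count of 974 genes was reached by 1 of 100 divisions of the libraries, the real one, with 559 as the highest other. Divisions that mix the groups of a cell line put its real changes into the replicate spread. A lower count there is therefore largely built in and does not test the difference.

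The first pattern weighed was the lower respiratory chain and cytosolic ribosomal lists without ALDH1B1. With the length and GC trend removed their medians moved from -0.20 (SE 0.03) to -0.14 (SE 0.02) and from -0.17 (SE 0.02) to -0.077 (SE 0.016), so the trend holds a part of both (camera, Benjamini-Hochberg adjusted p = 4.2e-13 and 3.1e-08). The respiratory chain list then also passed with an estimated correlation, while the ribosomal list, which had not passed before, did not (camera, Benjamini-Hochberg adjusted p = 0.033 and 0.28). Members with under 10% of exons shared stayed lower (limma's camera, 1.5e-07 and 8.4e-07 unadjusted and Benjamini-Hochberg adjusted p = 3.6e-07 and 1.7e-06 over 14 such tests, or 6.1e-06 and 2.3e-05 against protein-coding genes alone), as did reads summed with 47 and 322 pseudogenes (medians of -0.22, SE 0.03, and -0.18, SE 0.02). The trend alone does not account for the respiratory chain list, which passed with either correlation after its removal. For the ribosomal list the trend is not excluded, since only the preset correlation passed it. With that correlation, other divisions of the same libraries passed up to 18 lists. The tests of shared exons used it alone, so they exclude shared exons for neither list. The pseudogene sums, judged by their median and SE, argue against shared reads alone, though the trend was left in them. An effect of ALDH1B1 remains open beside these explanations and others that were not tested.

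The second pattern was the same lists with the inhibitor. With the trend removed their medians moved from -0.15 (SE 0.04) to -0.033 (SE 0.028) and from -0.11 (SE 0.02) to -0.026 (SE 0.016), each then within 2 SE of 0. Camera still passed both with the preset correlation (Benjamini-Hochberg adjusted p = 3.7e-07 and 7.6e-06) and neither with an estimated one (adjusted p = 0.45 and 0.66), so the trend and an effect of the inhibitor cannot be told apart. Members with little exon sharing stood at 0.0079 (SE 0.021) in the respiratory chain (limma's camera, 0.074 unadjusted and Benjamini-Hochberg adjusted p = 0.086, or 0.10 against protein-coding genes), where overlapping genes with the trend remain a candidate explanation, and at -0.022 (SE 0.015) in the ribosome (2.8e-05 unadjusted and adjusted p = 5.0e-05, or 9.5e-05), also within 2 SE of 0. The pseudogene sums stayed lower, at -0.073 (SE 0.036, narrowly past 2 SE) and -0.055 (SE 0.020). These sums were made with the trend left in, so their fall may come from it. They therefore do not decide whether shared reads contribute.

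The third pattern was the overlap of 242 genes changed in the same direction. With the length and GC trend removed 177 genes were lower in both, against 47.8 from independent lists, and 101 higher, against 39.4 (two-sided Fisher exact p = 1.6e-60 and 1.5e-19), so that trend alone does not account for the overlap. Of 29 genes lower in both by at least 0.5, 11 (37.9%) share at least 50% of their transcript, against 4.24% of other genes (two-sided Fisher exact p = 1.5e-08), so counting of overlapping genes may account for some of the largest shared falls. Among 12725 genes with under 10% shared, and with the trend left in, 115 were still lower in both, against 27.8, and 64 higher, against 22.6 (two-sided Fisher exact p = 6.7e-44 and 6.0e-15). The trend and the shared exons were not removed together, so their joint part in the overlap was not tested. A shared effect of lower ALDH1B1 activity stays open as a hypothesis.

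For each comparison of 3 libraries with 3, 10 divisions are too few for a share under 0.05. In the knockout clone 1 of 10 gave as many genes, with 3059 against 0 as the highest other, and the lists numbered 19 against 18. With the inhibitor the genes numbered 712 against 1 and the lists 11 against 10. In both comparisons the other divisions mix the groups, so their low gene counts are largely built in and do not test the calls. The 242 same-direction genes were reached by 1 of 100 divisions, the real one, with 0 as the highest other, but divisions that call at most 1 gene cannot share more, so that count says nothing on whether the changes are shared. The 0 genes came from edgeR with Benjamini-Hochberg adjustment, and counts of those divisions by another tool or at an unadjusted p were not computed.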

How the results depend on the processing

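The length and GC offset and the family list without ALDH1B1 were the alternatives chosen after the data were seen. For the knockout comparison the 3059 genes ranged from 1371 to 3951 on leaving out 1 library and the 166 changed at least 2-fold from 101 to 211, with 1670 genes (107 at least 2-fold) without ALDH1B1 replicate 1, 1371 (101) without ALDH1B1 replicate 2 and 1907 without EGFP replicate 1. For the inhibitor the 712 genes ranged from 171 to 832 and the 29 from 14 to 34, with 171 (18) without DMSO replicate 3, 178 (14) without inhibitor replicate 3 and 447 without the unnumbered library. The 974 genes that differed ranged from 392 to 1003 and the 116 at least 2-fold from 58 to 122, the 242 same-direction genes from 79 to 311, r from 0.11 to 0.21 and the lists from 16 to 20 and from 10 to 16. Leaving out libraries ended the calls of 4 named genes in the knockout comparison and 19 in the inhibitor comparison. DESeq2 gave 85 genes at least 2-fold in the knockout comparison and 14 in the inhibitor comparison. No filter on low counts gave 1402 genes for the inhibitor, 66 of them at least 2-fold, 422 same-direction genes, and a difference split of 422 higher and 459 lower. One fit over all 12 libraries gave 590 higher and 431 lower with the inhibitor. With an estimated correlation 6 and 0 lists passed, and fry passed 0 of the 11 inhibitor lists and 1 other, the lysosomal list. In the knockout comparison fry ended the call of 1 list, the mitochondrially encoded genes (fry, Benjamini-Hochberg adjusted p = 0.36), and passed 5 that camera had not. At a mean of at least 5 CPM r was 0.30. MT-ND6 turned to 0.049 with the length and GC offset (edgeR, Benjamini-Hochberg adjusted p = 0.60), which by construction removes the trend of short transcripts. The cause of the other shifts was not tested.

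Same-numbered libraries correlated at 0.083, -0.048 and 0.24 in the knockout comparison and at -0.067 and -0.10 in the inhibitor comparison, where 1 library has no number, so the numbers were not taken to pair them. EGFP replicate 2 correlated best with ALDH1B1 replicate 1, at 0.30, and inhibitor replicate 3 with DMSO replicate 1, at 0.39. The unnumbered inhibitor library correlated best with DMSO replicate 2, whose number its group lacks, at 0.30, so a pairing of these libraries stays possible. The replicate block gave 3563 genes for the knockout, 548 for the inhibitor (198 higher, 350 lower), 466 for the difference (59 at least 2-fold) and 212 in the same direction. In it DMSO replicate 2 and the unnumbered inhibitor library each formed a block of their own. The inhibitor values of that fit therefore rested on inhibitor and DMSO replicates 1 and 3 alone, as did the inhibitor side of the difference. In that fit 19 and 9 lists passed, and 4 of the 11 inhibitor lists (aldehyde dehydrogenase, ATF4, YAP and mesenchymal) and 8 named genes of the inhibitor comparison (KRT6A, MKI67, FDFT1, SREBF2, ALDH6A1, SPATA7, FGF19 and TIPARP) did not.

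Counts of genes and lists stayed within 1.5 times with relative log expression size factors and with the offset, apart from 57 opposite calls in place of 34 with the offset, and every named gene in both comparisons kept its call with those size factors.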

Other observations

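The comparison of the clone with the parental line was set up and its genes were chosen after the data were seen, while the test of aryl hydrocarbon receptor targets followed the rise of CYP1A1 but was set out before its own result.

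The knockout clone carrying ALDH1B1 and the parental line in DMSO were far apart. They differ at once in clone, knockout, expression construct and vehicle, so no part of the difference can be assigned to ALDH1B1. Of 18104 genes tested, 14137 passed an adjusted p of 0.05 (edgeR, Benjamini-Hochberg), 7043 higher and 7094 lower in the clone, and 6640 changed at least 2-fold. ATF4 targets fell in 39 of 41 cases and rose in 1 (39 and 1 adjusted over the list alone). The list was lower (camera, Benjamini-Hochberg adjusted p = 5.1e-28, adjusted p = 0.061 with an estimated correlation), with TRIB3 at 96.1 ± 3.6 CPM (SD, n = 3) in the clone and 1487 ± 38.0 CPM (SD, n = 3) in the parental line and SLC7A11, a cystine transporter gene, at 17.2 ± 1.8 and 194 ± 12.02 CPM (SD, n = 3). YAP targets rose in 18 of 22 cases and fell in 3 (18 and 3 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 4.2e-09, adjusted p = 0.20 with an estimated correlation), with ANKRD1 at 191 ± 9.8 against 7.23 ± 0.52 CPM and CRIM1 at 182 ± 1.9 against 3.47 ± 0.44 CPM (SD, n = 3).

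Mesenchymal genes rose in 19 of 27 cases and fell in 8 (19 and 8 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 5.0e-05, adjusted p = 0.099 with an estimated correlation), VIM by 4.44 (SE 0.06) and FN1 by 4.07 (SE 0.09). Of the VIM transcript 46.0% is shared with other genes, an antisense gene among them. Epithelial junction genes fell in 13 of 25 cases and rose in 9 (13 and 9 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 6.1e-05, adjusted p = 0.22 with an estimated correlation), with EPCAM at -2.52 (SE 0.04) and CDH1 at -3.003 (SE 0.08). VIL1, an enterocyte brush border gene that shares 46.6% of its transcript, stood at 0.143 ± 0.083 CPM (SD, n = 3) in the clone and 341 ± 10.5 CPM (SD, n = 3) in the parental line. Heat shock genes rose in 16 of 19 cases and fell in 1 (16 and 1 adjusted over the list alone). G1/S genes rose in 39 of 44 cases and fell in 2 (39 and 2 adjusted over the list alone). Both lists were higher (camera, Benjamini-Hochberg adjusted p = 3.4e-08 and 4.2e-09, adjusted p = 0.099 and 0.22 with an estimated correlation), including HSPB1 at 2.72 (SE 0.06) and MCM2, which shares 31.97% of its transcript, at 1.93 (SE 0.04). Other divisions of these 6 libraries, 10 in all and too few for a share under 0.05, gave at most 0 genes, against 14137 in 1 of them. Divisions that mix the groups give low gene counts largely by construction.

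A hypothesis from the rise of CYP1A1 was that targets of the aryl hydrocarbon receptor rise together with the inhibitor. Among 8 tested targets without CYP1A1 the median was 0.20 and the list was higher (limma's camera, 0.0020 unadjusted and Benjamini-Hochberg adjusted p = 0.0099 over 43 lists). It did not pass with an estimated correlation (adjusted p = 0.41 with an estimated correlation). Past 0.05 on their own were AHRR, at 0.33 (SE 0.06), and TIPARP, at 0.20 (SE 0.05; edgeR, Benjamini-Hochberg adjusted p = 0.0059 and 0.040). TIPARP lost its call without DMSO replicates 1, 2 or 3, inhibitor replicate 3 or the unnumbered inhibitor library (edgeR, Benjamini-Hochberg adjusted p up to 0.21). Activation of that receptor by the compound may contribute, and whether it passes through ALDH1B1 was not tested. In the knockout comparison CYP1A1 was at 0.36 (SE 0.20; edgeR, Benjamini-Hochberg adjusted p = 0.23), AHRR at 0.33 (SE 0.07; edgeR, Benjamini-Hochberg adjusted p = 0.0061) and TIPARP at 0.0092 (SE 0.054; edgeR, Benjamini-Hochberg adjusted p = 0.93).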
